A study of Homo sapiens with 4 samples.

How the data were processed

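The series is a pooled CRISPR/Cas9 knockout screen in THP-1, a human monocytic leukaemia cell line that was made to express Cas9. Per the labels' protocols, the cells received the Brunello library, a lentiviral collection of single guide RNAs (sgRNAs) against human protein-coding genes, at an infection ratio of 0.2, and were kept on puromycin for 3 days. The stated aim was at least 500 cells per sgRNA. Cells were primed with lipopolysaccharide (LPS) for 3 hours and then given either vehicle (DMSO) or R837 with Yoda1. R837 (imiquimod) is a TLR7 agonist that also activates the NLRP3 inflammasome, and Yoda1 opens the mechanosensitive ion channel PIEZO1. The drugs were removed when about 85% of the treated cells had died by pyroptosis, the survivors were grown, and the same selection was applied again. Guide cassettes were then amplified by PCR from genomic DNA and sequenced.

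The authors deposited 1 table of raw read counts per sgRNA for 4 libraries, 2 of vehicle and 2 of treated survivors, per the file headers. The submitters' processing notes list bcl2fastq 2.20.0.422, Bowtie2 and MAGeCK 0.5.9.3 with the build hg38, without saying what each did. No molecular identifiers are mentioned, so reads of a guide are not independent molecules and any interval given covers counting error only. The table held 77441 sgRNAs, of which 1000 were non-targeting, and 19114 gene symbols. Of these symbols, 17849 were current in the RefSeq table of GRCh38.p14, 1110 were older symbols and were updated through it, and 155 had no match and were kept as written. Gene coordinates are the RefSeq gene bounds on that assembly. The guide sequences are not part of the table used here, so cut sites and additional matches in the genome were not analysed here.

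Total counts were 41767983 and 30709876 reads in vehicle replicates 1 and 2, and 72308939 and 59420755 reads in treated replicates 1 and 2. Guides with a mean count of at least 10 over the 4 libraries were kept, which left 75355. Library sizes were scaled with TMM. Guides were tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3) for treated against vehicle, with Benjamini-Hochberg adjustment over the guides and a threshold of 0.05. Genes were ranked by robust rank aggregation (alpha 0.25) of the signed square root of the edgeR F statistic, in each direction separately. Their one-sided p came from a permutation test on 1000000 random guide sets of the same size, so that 1e-06 is the smallest p it can give, with Benjamini-Hochberg adjustment over the 19028 genes that had at least 2 tested guides. MAGeCK itself was not run here. A reimplementation of its guide model served as an alternative.

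Gene-level changes are differences of log2(CPM + 1), averaged over the tested guides of a gene, and are given as the mean ± SD over the 2 same-numbered pairs of libraries. This SD leaves out differences between guides, which can cancel in the gene mean. The scale understates the change of rare guides. Gene lists were tested with limma 3.58.1 (camera, two-sided, preset inter-gene correlation 0.01) on these gene values, with Benjamini-Hochberg adjustment over the 25 lists. List medians are given relative to the median of all genes. Beside each list stands the number of members that passed over all genes, and the number adjusted over the list alone. The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took up to 15 enriched genes and 8 depleted genes past the threshold with the smallest p and at least 2 guides moving the same way in both pairs, 12 genes named in advance, and up to 4 members of each list with the smallest p. It gave 10 enriched and 8 depleted genes.

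The series text states that vehicle and surviving cells were sequenced for each replicate, so the replicate numbers were taken to pair the libraries. The deviations of same-numbered libraries from their group means correlated at 0.67 across guides. The main model has no replicate term, and the model with the replicate number as a block is given beside a result where it changes the call or moves a count by more than 1.5 times. Nothing in the sources used here says whether the replicates were separate cultures or infections. The p-values of guides and of limma on gene means therefore measure only the spread between these libraries, which may be technical. Gene p-values by rank aggregation compare the ranks of a gene's guides with random guide sets. They measure agreement between guides, not between replicates. Camera p-values compare the genes of a list with the other genes.

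The scripts were tested on simulated counts with 200 changed genes at the common dispersion of the edgeR model. The simulated counts held no replicate effect, and all guides of a gene changed alike. The rates below therefore need not hold for the real libraries, which differed by replicate number. Over 19042 genes, the gene test recovered 4% of the genes raised by 1 on the log2 scale, 72% of those raised by 2, 6% of those lowered by 1 and 81.2% of those lowered by 2, and called 4 of 18844 unchanged genes. The edgeR guide test called 0 guides, although 781 belonged to changed genes, so a guide count of 0 from this model without a block says little. DESeq2 1.42.0 called 31 of those guides and also 18 unchanged guides. The MAGeCK-style model called 276 of them and also 9.81% of the unchanged guides.

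The alternatives were other scalings (DESeq2 size factors, total counts, non-targeting guides), no count filter or a mean of at least 100, the replicate block, each library left out, the DESeq2 Wald test, the MAGeCK-style guide model, limma on gene means, each gene without its strongest guide, rank aggregation with alpha 0.1 or without alpha, each pair alone, a prior of 5 CPM, camera with an estimated correlation, fry, and permutation of gene labels. Scaling by total counts moved the median change of all guides from -0.10 to -0.65, and scaling on non-targeting guides moved it to -0.24. Changes are therefore relative to the other guides of the library. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the remaining steps. Of the 7 gene groups tested on their other members, the result of 1 is not reported here.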

Results

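The abundance of 77441 sgRNAs was measured in 4 libraries of LPS-primed THP-1 cells, 2 from vehicle-treated cells and 2 from cells that had survived repeated selection with R837 and Yoda1. Sequencing gave 41767983 and 30709876 reads for vehicle replicates 1 and 2, and 72308939 and 59420755 for treated replicates 1 and 2. The median guide had 259 and 303 reads in the vehicle libraries and 276 and 381 in the treated libraries. Between 932 and 1169 guides had no read in a given library, and 801 had none in any. Read counts were uneven: the Gini index was 0.633 and 0.447 in the vehicle libraries and 0.753 and 0.628 in the treated libraries, and the top 1% of guides held 18.1% and 8.24% against 34.6% and 22.5% of the reads. A single guide against DEFB132, a defensin gene, was the most abundant in each library, with 1.13% (95% Wilson interval 1.13 to 1.13) and 0.808% (0.805 to 0.812) of vehicle reads and 5.04% (5.04 to 5.05) and 2.92% (2.92 to 2.93) of treated reads. These intervals cover counting error only.

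The libraries differed by replicate number as well as by treatment. Across 75355 guides, which are not independent replicates, log2(CPM + 1) correlated at a Pearson r of 0.931 between vehicle and treated replicate 1 and at 0.865 between those of replicate 2. It correlated at 0.784 between the vehicle libraries and at 0.887 between the treated libraries. Treated replicate 2 was as close to vehicle replicate 1 (0.868) as to vehicle replicate 2. The 1480 guides with at least 5000 reads in treated replicate 1 had a median of 0.568 times as many in treated replicate 2 (5th to 95th percentile 0.428 to 0.791). Guides against genes that proliferating cells need were rarer in replicate 1: the median guide against cytosolic ribosomal proteins had 0.0133 and 0.0550 times the reads of the median non-targeting guide in vehicle replicates 1 and 2, and 0.00904 and 0.0268 times in treated replicates 1 and 2. Control guides gave the background. The 992 non-targeting guides had a median log2 change of 0.04 (SD 0.55), and 1476 guides against olfactory receptors, which monocytes do not need, had a median of -0.04 (SD 0.68). Scaling by total counts placed the non-targeting median at -0.50 and scaling on the non-targeting guides placed it at -0.08. Of 248 sets of 4 non-targeting guides, 0 passed the enrichment or depletion test by rank aggregation of edgeR statistics, with 7 and 0 at an unadjusted p under 0.05. With the replicate block 0 passed after adjustment. Non-targeting guides were more abundant than the median guide (826 against 259 reads in vehicle replicate 1). Their changes also spread less than those of all guides (SD 0.55 against 0.74). These sets therefore say little about false calls among rarer guides.

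The first question of the screen was which knockouts were more frequent among cells that survived R837 and Yoda1. Guides against 10 of 19028 genes were enriched. Both NLRP3, the sensor of the inflammasome that R837 activates, and PYCARD, which encodes the adaptor ASC that links this sensor to caspase-1, were among them, with mean log2 changes of 1.58 ± 0.01 and 2.28 ± 0.16 (SD over replicates, n = 2). The 2 subunits of a phospholipid flippase of the plasma membrane also rose, the P4-ATPase ATP11A by 2.08 ± 0.02 and its partner TMEM30A by 1.96 ± 0.09. IKBKB, the kinase that releases NF-kB from its inhibitors, rose by 2.05 ± 0.02, and GANAB, the catalytic subunit of glucosidase II that trims N-glycans in the endoplasmic reticulum, by 1.93 ± 0.04. The remaining genes were the acetyltransferase CREBBP (1.77 ± 0.03), the poly(A) polymerase PAPOLA (1.56 ± 0.76), the nuclear receptor NR2C2 (1.30 ± 0.05) and the deubiquitinase USP47 (1.21 ± 0.14).

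All 4 guides of each of these genes were higher in both replicates, except for NLRP3 with 3 of 4. The small SD of NLRP3 hides guides that differed between replicates 1 and 2. A guide had 0.465 and -0.483, and another had 1.63 and 2.38. By rank aggregation of edgeR statistics with Benjamini-Hochberg adjustment, PAPOLA, ATP11A, GANAB, NLRP3 and CREBBP had an adjusted p of 0.00381 from the smallest p the permutations can give (1e-06). The adjusted p was 0.00476 for PYCARD, TMEM30A and USP47, 0.00634 for IKBKB and 0.0438 for NR2C2. Over the 19 alternatives USP47 passed in 7 and NR2C2 in 9: USP47 was lost with total-count scaling (0.0851), non-targeting scaling (0.052) and the MAGeCK-style model (0.0501), and NR2C2 with DESeq2 size factors (0.0571). With the replicate number as a block, 18 genes were enriched, the 10 genes above among them. The count was 0 without vehicle replicate 1 (1019 genes at an unadjusted p under 0.05), 2 without vehicle replicate 2, 4 without treated replicate 1 and 0 without treated replicate 2 (1041 at an unadjusted p under 0.05). Of the 10 genes, PAPOLA passed without vehicle replicate 2, and PAPOLA, NLRP3 and ATP11A passed without treated replicate 1. The median log2 change of the PAPOLA guides fell from 2.12 to 0.77 without treated replicate 2 (adjusted p = 0.605). When each gene lost its strongest guide, 2 passed (PAPOLA and ATP11A). limma on gene means called 0 genes enriched (335 at an unadjusted p under 0.05), and 563 with the block. The unadjusted counts given here lay near or below the share of 0.05 that can pass if no gene changed.

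**Figure D1:**
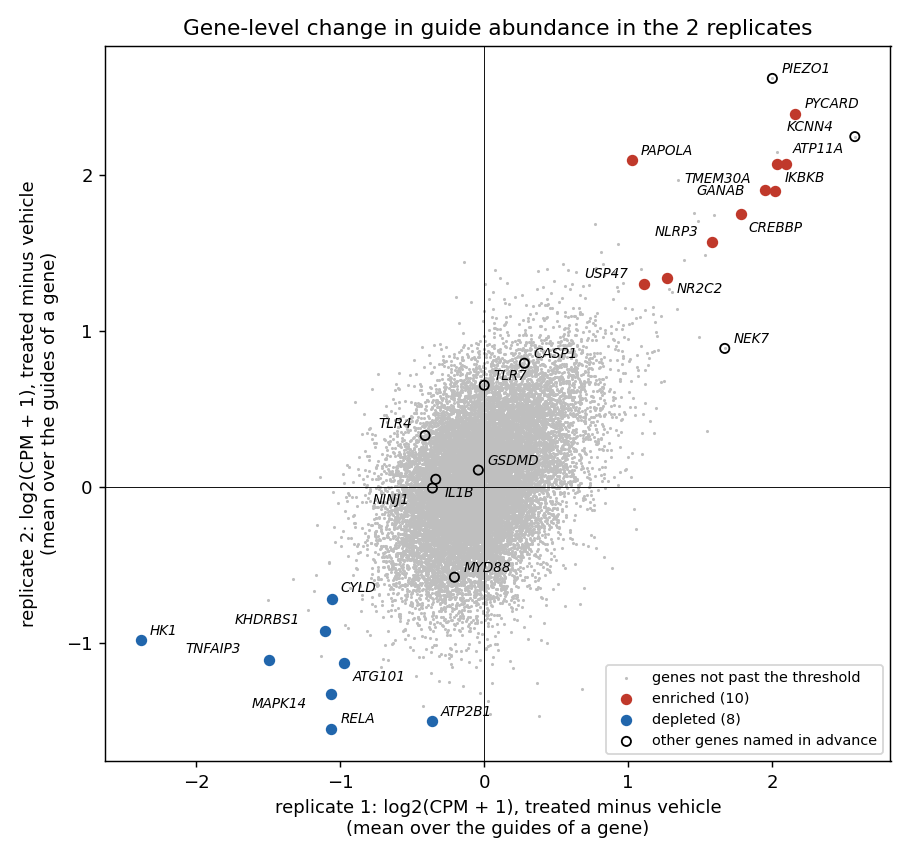
Each point is a gene, placed by the change of log2(CPM + 1) from vehicle to treated cells, averaged over its guides, in replicate 1 (horizontal axis) and replicate 2 (vertical axis). The 10 enriched genes (red) lie above 1 in both replicates, the 8 depleted genes (blue) lie below 0 in both, and PIEZO1 and KCNN4 (open circles) have means of 2.31 and 2.41.

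Guides against the target of Yoda1 and against a calcium-gated potassium channel had the highest gene means among the genes named in advance. PIEZO1, the mechanosensitive cation channel that Yoda1 opens, had a mean log2 change of 2.31 ± 0.43 (SD over replicates, n = 2), and KCNN4, which encodes the potassium channel KCa3.1, had 2.41 ± 0.23. Each of their 4 guides was higher in both replicates. Neither gene passed by rank aggregation of edgeR statistics without the replicate term (adjusted p = 0.215 for each with Benjamini-Hochberg adjustment). Both passed with the replicate block (0.00159 for each). Over the 19 alternatives the adjusted p ranged from 0.00159 to 1, with 9 past the threshold for PIEZO1 and 8 for KCNN4. The most abundant guide against PIEZO1 went from 21994 to 162223 reads in replicate 1 and from 11839 to 90690 in replicate 2, and the most abundant guide against KCNN4 went from 11692 to 75981 and from 5686 to 46854. The 16 guides of PIEZO1, KCNN4, PYCARD and NLRP3 had a median of 6.80 and 7.42 times the raw vehicle reads in replicates 1 and 2. The 36 most abundant guides of the treated libraries had a median of 6.61 and 7.01 times. These ratios are not scaled for sequencing depth. Scaled on non-targeting guides, the ratio of the 36 guides was 5.48 and 4.97.

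Of the 12 genes named in advance, NLRP3 and PYCARD passed as given above, and the 8 besides PIEZO1 and KCNN4 did not. CASP1, the protease that cleaves gasdermin D, had a mean log2 change of 0.54 ± 0.36 (SD over replicates, n = 2) with 3 of 4 guides higher in both replicates. Its adjusted p by rank aggregation of edgeR statistics was 0.931. GSDMD, which encodes the pore-forming gasdermin D, had 0.03 ± 0.10, and NINJ1, which ruptures the plasma membrane late in lytic death, had -0.18 ± 0.25. NEK7, a kinase that binds NLRP3, had 1.28 ± 0.56 over 2 tested guides, an adjusted p of 0.856, and 2 further guides with too few reads. The LPS receptor TLR4 stood at -0.04 ± 0.52, the adaptor MYD88 at -0.39 ± 0.26, the R837 receptor TLR7 at 0.33 ± 0.46 and the cytokine gene IL1B at -0.14 ± 0.27. Their adjusted p values were 0.766 or higher in both directions.

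**Figure D2:**
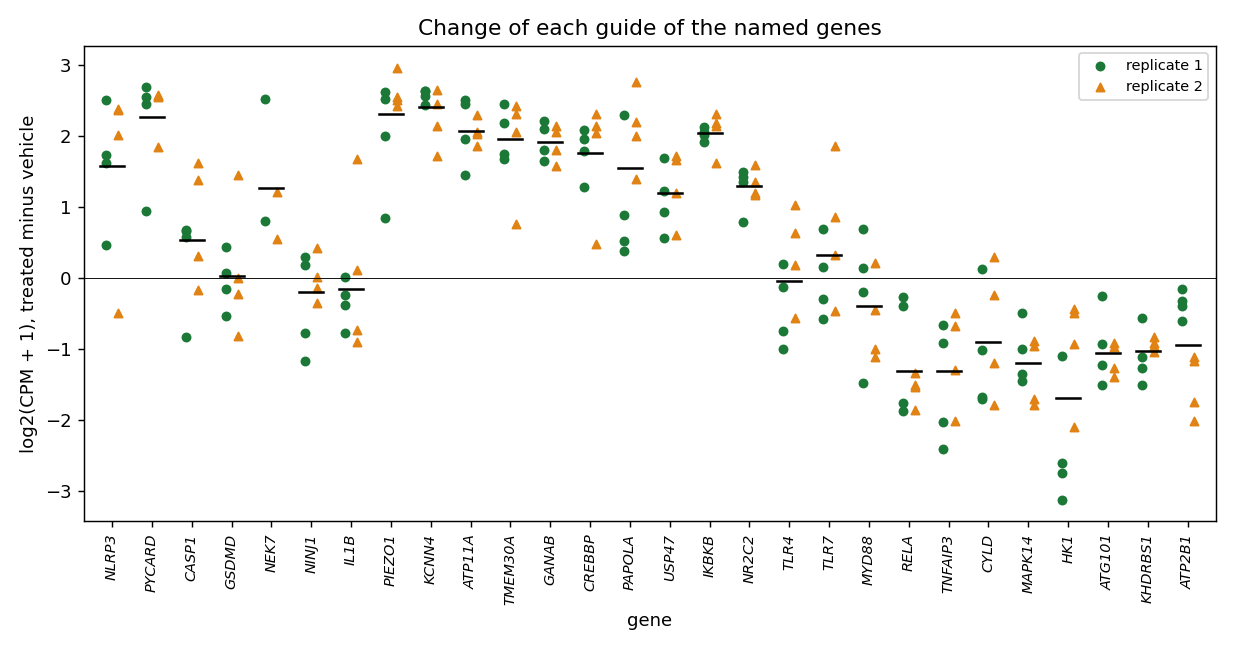
Points are single guides of the named genes, at their change of log2(CPM + 1) from vehicle to treated cells in replicate 1 (green circles) and replicate 2 (orange triangles), and black lines are the mean over guides and replicates. The lines of PIEZO1 (2.31), KCNN4 (2.41) and PYCARD (2.28) are the highest, those of GSDMD (0.03) and TLR4 (-0.04) are near 0, and that of HK1 (-1.69) is the lowest.

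The second question was which knockouts were rarer among the survivors. Guides against 8 genes were depleted. HK1, the hexokinase that starts glycolysis and sits on mitochondria, fell by 1.69 on the log2 scale (SD 0.99, n = 2 replicates), from -2.39 in replicate 1 and -0.99 in replicate 2. RELA, the p65 subunit of NF-kB, had a change of -1.31 ± 0.35, and TNFAIP3 (A20) and CYLD, a pair of deubiquitinases that restrain NF-kB signalling, had -1.31 ± 0.27 and -0.89 ± 0.24. The stress kinase p38-alpha gene MAPK14 (-1.20 ± 0.19), the autophagy initiation gene ATG101 (-1.05 ± 0.11), the RNA-binding protein gene KHDRBS1 (-1.02 ± 0.13) and the plasma membrane calcium pump gene ATP2B1 (-0.93 ± 0.81) completed the set.

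All 4 guides of each depleted gene were lower in both replicates, except for CYLD with 2 of 4. By rank aggregation of edgeR statistics with Benjamini-Hochberg adjustment, HK1, TNFAIP3, MAPK14, RELA and ATG101 had an adjusted p of 0.00381, CYLD 0.00634, KHDRBS1 0.0245 and ATP2B1 0.0499. With the replicate block 8 genes were depleted, 7 of them shared: CYLD had an adjusted p of 0.486, and HSP90B1, the endoplasmic reticulum chaperone gp96, passed at 0.0272. Over the 19 alternatives the adjusted p of CYLD ranged from 0.00317 to 1, and CYLD and KHDRBS1 passed in 8 each and ATG101 and ATP2B1 in 10 each. KHDRBS1 was lost with total-count scaling, ATP2B1 with DESeq2 size factors, and CYLD, KHDRBS1 and ATP2B1 with a mean count of at least 100. The count was 6 without vehicle replicate 1, 5 without vehicle replicate 2, 2 without treated replicate 1 and 4 without treated replicate 2. Of the 8 genes, RELA, ATP2B1 and MAPK14 passed without vehicle replicate 1, HK1 and TNFAIP3 passed without vehicle replicate 2 and without treated replicate 1, and HK1, TNFAIP3 and MAPK14 passed without treated replicate 2. The median log2 change over guides moved from -2.23 to -0.85 for HK1 and from -1.35 to -0.78 for CYLD without vehicle replicate 1, and from -1.51 to -0.76 for MAPK14, from -2.13 to -0.79 for ATP2B1 and from -2.18 to -1.44 for RELA without vehicle replicate 2. When each gene lost its strongest guide, 3 passed (HK1, MAPK14 and RELA). limma on gene means called 0 genes depleted (149 at an unadjusted p under 0.05), and 296 with the block.

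Each pair of libraries was also ranked alone, without replicate error. The pairs called 13 and 14 genes enriched, of which 10 were shared (ATP11A, CREBBP, GANAB, HOXA13, IKBKB, KCNN4, NLRP3, PIEZO1, PYCARD and TMEM30A). Independent lists of these sizes would share 0.0096. The pairs cannot be taken as independent, because the treated libraries shared their abundant guides, so the overlap does not show separate replication. They called 4 and 2 genes depleted, of which 0 were shared: HK1, HSP90B1, TNFAIP3 and SFRP1 in replicate 1, and RELA and ATP2B1 in replicate 2. At the level of single guides, the edgeR quasi-likelihood test called 0 of 75355 (1595 at an unadjusted p under 0.05), and DESeq2 called 0 (3574 at an unadjusted p under 0.05). Both unadjusted counts lay below the share of 0.05 that can pass if no guide changed. With the replicate block edgeR called 3149 guides, 2614 higher and 535 lower, and the MAGeCK-style model called 6132.

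On GRCh38, the enriched genes lay as follows: NLRP3 on chromosome 1 from 247416077 to 247448817, PYCARD on chromosome 16 from 31201486 to 31202760, ATP11A on chromosome 13 from 112690038 to 112887168, TMEM30A on chromosome 6 from 75252924 to 75284792, IKBKB on chromosome 8 from 42271302 to 42332460, GANAB on chromosome 11 from 62624829 to 62646613, CREBBP on chromosome 16 from 3725054 to 3880713 and PAPOLA on chromosome 14 from 96502376 to 96567116. PIEZO1 spans 88715338 to 88785220 of chromosome 16 and KCNN4 spans 43766533 to 43780973 of chromosome 19. Among the depleted genes, HK1 spans 69270000 to 69401882 of chromosome 10, RELA 65653601 to 65663857 of chromosome 11, TNFAIP3 137866349 to 137883312 of chromosome 6 and MAPK14 36027808 to 36124214 of the same chromosome. The library targets coding exons. The exon cut by each guide was not analysed here.

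Pathway-level changes were examined next, with 25 gene lists fixed in advance. The NLRP3 inflammasome and pyroptosis core rose, with a median 0.92 above that of all genes on the log2 scale over 6 genes. Of these, 2 rose (NLRP3 and PYCARD, also when adjusted over the list alone) and 4 did not pass. The list call ended in camera with an estimated correlation (adjusted p = 0.70). That estimate was -0.14, below the preset 0.01, so correlation between members does not account for the loss. The 28 genes that build and attach glycosylphosphatidylinositol (GPI) anchors, the lipid tethers of some surface proteins, rose by a median of 0.35, with 23 members above 0 and 5 below. This call also ended in camera with an estimated correlation, here 0.13 (adjusted p = 0.70). Of single members, 0 passed over all genes or adjusted over the list alone (rank aggregation of edgeR statistics), with 10 of 28 at unadjusted p values under 0.05. The lowest were PIGY (0.90 ± 0.34, SD over replicates), PIGT (0.56 ± 0.28), DPM1 (0.69 ± 0.31) and PIGM (0.72 ± 0.12).

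Camera of limma with Benjamini-Hochberg adjustment gave an adjusted p of 7.1e-06 for the inflammasome core and 2.3e-06 for GPI anchor synthesis. Both calls held without each library in turn (highest adjusted p 0.000397 and 0.00184). With an estimated correlation neither held, and no list of the 25 passed in that setting or by fry. On simulated counts, a list of 30 raised genes had an unadjusted p of 8.55e-24 by camera with the preset correlation. With an estimated correlation its unadjusted p was 0.00756. A call lost in that setting therefore says little about a list.

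Genes of endosomal nucleic acid sensing through TLR7 and TLR8 fell by a median of 0.25 below all genes over 15 genes, with 13 members below 0. The 2 members above 0 were the R837 receptor TLR7 itself (0.33) and TLR9 (0.43). The median was -0.438 without vehicle replicate 1 and -0.079 without vehicle replicate 2. In camera with an estimated correlation the call ended (adjusted p = 0.70), although the estimate of 0.0068 lay below the preset 0.01. Of the 15 genes, 0 passed over all genes by rank aggregation, and 3 fell when adjusted over the list alone: TLR8, a receptor for RNA (-0.62 ± 0.11), and CNPY3 (-0.65 ± 0.27) and HSP90B1 (-1.11 ± 0.55), a chaperone pair that folds Toll-like receptors. The list had an adjusted p of 0.0047 by camera of limma and 0.0631 when libraries were scaled by total counts. The V-ATPase, the proton pump that acidifies endosomes and lysosomes, fell by a median of 0.27 over 16 genes, with 15 below 0, and ATP6V1A (-0.78 ± 0.58) was the 1 member that fell when adjusted over the list alone. Its adjusted p was 0.023 by camera of limma and 0.94 with an estimated correlation. The V-ATPase call ended without vehicle replicate 2 (median 0.13, adjusted p = 0.985) and without treated replicate 1 (-0.21, adjusted p = 0.274), and with scaling on total counts (0.766) or non-targeting guides (0.118) or a mean count of at least 100 (0.824). Guides against ribosomal proteins, which like the V-ATPase are needed by most proliferating cells, had median reads of 0.0133 and 0.0550 times the median of non-targeting guides in vehicle replicates 1 and 2.

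**Figure D3:**
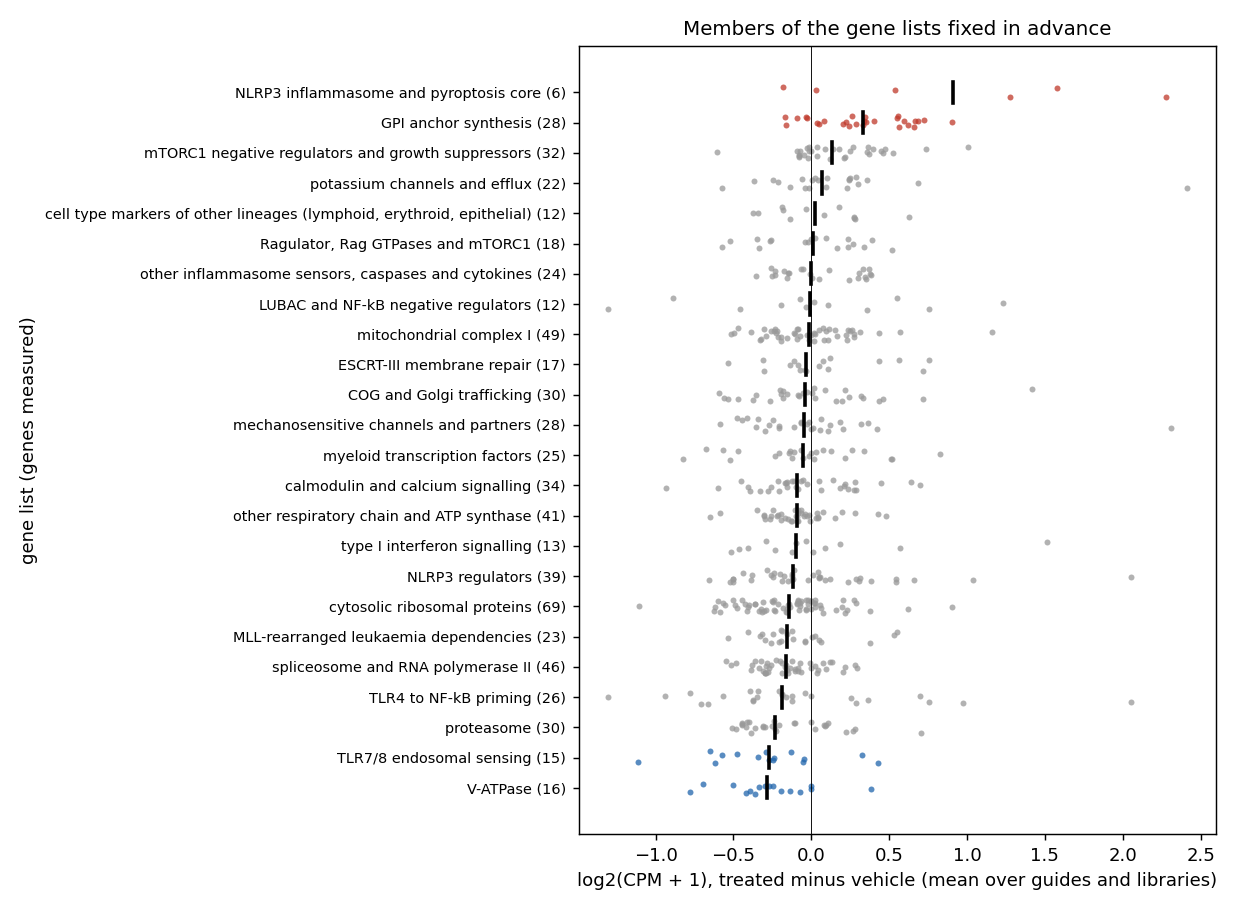
Points are the genes of each list fixed in advance, at their change of log2(CPM + 1) from vehicle to treated cells (horizontal axis), and black bars are the list medians, with the number of genes measured in parentheses. The NLRP3 inflammasome core and GPI anchor synthesis (red) rose and TLR7/8 sensing and the V-ATPase (blue) fell by camera with the preset correlation, and the olfactory receptors are not drawn.

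The signalling lists held members that moved in opposite directions. In the chain from TLR4 to NF-kB (26 genes, median -0.17 relative to all genes, adjusted p = 0.065 by camera of limma), IKBKB rose, RELA fell and 24 did not pass. The list passed without vehicle replicate 2 (0.0236) and without treated replicate 1 (0.0435). Adjusted over the list alone, IKBKB, IKBKG (0.97 ± 0.04) and IRAK2 (0.75 ± 0.23) rose, whereas RELA, CHUK (-0.94 ± 0.31) and IRAK1 (-0.78 ± 0.41) fell. TIRAP (-0.35 ± 0.30) passed towards lower values with 2 of 4 guides lower and 1 higher in both replicates. IKBKG and CHUK encode the other subunits of the IkB kinase complex, and IRAK1, IRAK2 and TIRAP act just below the receptor. Among 12 genes of the linear ubiquitin ligase LUBAC and the negative regulators of NF-kB (adjusted p = 0.88), CYLD and TNFAIP3 fell. Adjusted over the list alone, RNF31 (1.23 ± 0.38), the catalytic subunit of LUBAC, and NFKBIA (0.76 ± 0.27), an inhibitor of NF-kB, also rose. Among 39 regulators of NLRP3 (adjusted p = 0.84), IKBKB rose, and adjusted over the list alone ZDHHC7 (1.04 ± 0.01) rose and NEK9 (-0.66 ± 0.09) fell. PLK1 (0.28 ± 0.26) passed towards higher values on 1 guide, with 1 of 4 guides higher and 2 lower in both replicates.

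Of the transporter and trafficking lists, none passed by camera of limma. The 22 potassium channel genes (adjusted p = 0.47) and the 28 mechanosensitive channels and partners (0.43) each had 1 member that rose when adjusted over the list alone, KCNN4 and PIEZO1, and 0 over all genes by rank aggregation without the block. Without treated replicate 1 the mechanosensitive list passed towards lower values (adjusted p = 0.0435). Among 34 genes of calmodulin and calcium signalling (0.68), ATP2B1 fell. Of 30 genes of Golgi trafficking and the COG complex (0.99), SLC35A2, the Golgi transporter of UDP-galactose (1.42 ± 0.05), rose when adjusted over the list alone and also with the replicate block (adjusted p = 0.0203 by rank aggregation). ESCRT-III membrane repair (17 genes, 0.47), the Ragulator and mTORC1 complexes (18 genes, 0.91), other inflammasome sensors, caspases and cytokines (24 genes, 0.68) and type I interferon signalling (13 genes, 0.68) had 0 members past either adjustment, with 2 to 6 of their members at an unadjusted p under 0.05. For 8 of the 25 lists, 0 of them past the threshold, the relative median, the mean and the camera direction differed in sign, among them LUBAC, COG and Golgi trafficking, mechanosensitive channels and type I interferon signalling.

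Lists on growth and identity were tested to follow the fitness of the cells. The 32 negative regulators of mTORC1 and growth lay 0.15 above all genes (adjusted p = 0.065 by camera of limma, 0.042 with the replicate block and 0.0306 without treated replicate 1), with CBL (0.73 ± 0.53), TBC1D7 (1.01 ± 0.52) and TSC1 (0.53 ± 0.43) among those above 0. KEAP1 (-0.61 ± 0.57) went the other way with the lowest unadjusted p of the list, and no member passed. The 69 cytosolic ribosomal protein genes lay at -0.13 (0.10, and 0.042 with the block). They passed without vehicle replicate 1 (3.85e-05) and without treated replicate 2 (0.0252), and lay at 0.03 with an adjusted p of 0.039 when libraries were scaled by total counts. The proteasome (30 genes, 0.33), the spliceosome and RNA polymerase II (46 genes, 0.16), mitochondrial complex I (49 genes, 0.96), the rest of the respiratory chain (41 genes, 0.43) and dependencies of MLL-rearranged leukaemia (23 genes, 0.57) did not pass. By camera, complex I passed with total-count scaling (adjusted p = 0.00716) and the spliceosome list with DESeq2 size factors (0.0461). Without vehicle replicate 1 the proteasome, spliceosome and respiratory chain lists did pass (0.000316, 0.000176 and 0.00505), and so did the spliceosome list without treated replicate 2 (0.0155). Among 25 myeloid transcription factors (0.68), GFI1 (-0.82 ± 0.26) and TBL1XR1 (-0.68 ± 0.30) fell when adjusted over the list alone. HDAC3 passed there towards lower values too, but the change was 0.18 in replicate 1 and -1.12 in replicate 2, with 0 of 4 guides lower in both. Markers of lymphoid, erythroid and epithelial cells (12 genes, 0.90) and 372 olfactory receptors (0.57) did not pass, although this last list passed by permutation of gene labels (0.017).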

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

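The replicate block combined with the removal of each gene's strongest guide was chosen after the data were seen, and the other alternatives were planned. Starting from 10 enriched and 8 depleted genes, the count was 17 and 13 with total-count scaling, 19 and 15 with the DESeq2 Wald test, 18 and 17 with the MAGeCK-style guide model, 2 and 3 when each gene lost its strongest guide, and 0 and 0 with limma on gene means (335 and 149 at an unadjusted p under 0.05). The pairs alone called 4 and 2 depleted genes. Without single libraries the counts lay between 0 and 4 enriched genes, and between 2 and 6 depleted genes. The other scalings, filters and alpha values gave 10 to 14 enriched and 6 to 11 depleted genes. The cause of these shifts was not tested, apart from the lower number of guides or libraries in some.

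With the replicate block, 18 genes were enriched and 3149 guides changed, against 10 and 0 (1595 guides at an unadjusted p under 0.05). In the paired model the calls of KCNN4 and PIEZO1 were gained and that of CYLD was lost, the ribosomal protein and mTORC1 lists passed, and no other call changed among the 28 genes that lead the comparisons or were named in advance, or among the 25 lists. The block without each gene's strongest guide gave 12 enriched and 2 depleted genes. The MAGeCK-style model called 6132 guides.

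Of 25 lists, 4 passed with TMM scaling and camera, 7 with DESeq2 size factors, 10 by permutation of gene labels, and 0 with an estimated correlation or by fry. The estimated correlation says little, because the camera p of a simulated changed list also rose there, from 8.55e-24 to 0.00756. Without single libraries between 4 and 8 passed, with 8 without vehicle replicate 1. The V-ATPase median, -0.27 relative to all genes, lay between -0.610 without vehicle replicate 1 and 0.130 without vehicle replicate 2, where it reversed, and the ribosomal proteins reversed from -0.127 to 0.0265 with total counts. The non-targeting median was -0.497 with total counts and -0.0833 with factors from non-targeting guides. The cause of these shifts was not tested. For named genes, 389 results kept their side of the threshold, 124 lost and 17 gained a call, and for lists 310 kept it, 13 lost and 25 gained a call. The Gini indices moved by less than the spread between replicates with the count filter. With 2 libraries per group the design has few residual degrees of freedom, and where 1 library is left in a group its spread is taken from the other group. Rare guides limit genes such as NEK7, where 2 of 4 guides were tested.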

Other observations

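The tests of shared abundance and of separate populations, of the common ceiling, of matching counts and of sample splits were chosen after the results were seen. The gene groups below were picked because some of their genes ranked near the top, and were tested on their other members, with the p values adjusted over 7 groups.

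Guides against the autophagy machinery lay low among the survivors: besides ATG101 and RB1CC1, a scaffold of the same initiation complex (-0.89 ± 0.31), the 14 other members had a mean of -0.33, with 12 below 0 (adjusted p = 0.0001 over 7 groups, one-sided permutation test of gene labels). ATG3, ATG7, ATG5 and ATG9A, which act in lipid conjugation and membrane supply, had -0.78, -0.74, -0.73 and -0.71. Without single libraries the mean of this group relative to all genes was between -0.419 and -0.238.

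Guides against N-glycan assembly and trimming lay high. Besides GANAB and SLC35A2, MOGS, the glucosidase that acts before glucosidase II, had 1.24 ± 0.44 and OST4, a subunit of the oligosaccharyltransferase, had 1.24 ± 0.14 (SD over replicates, n = 2), with adjusted p values of 0.0761 and 0.101 by rank aggregation of edgeR statistics. OSTC, another subunit, lay the other way at -0.87 ± 0.23. The 17 other members had a mean of 0.25, with 12 above 0, among them MGAT2 (0.76), PRKCSH (0.56) and MGAT1 (0.45) (adjusted p = 0.0025, one-sided permutation test). Their mean relative to all genes was 0.156 without treated replicate 1 and 0.333 without treated replicate 2. A further 4 groups did not pass: the GATOR2 complex (0.12), the HDAC3 corepressor complex (0.15), P4-ATPase flippases other than ATP11A (0.21) and the p38 pathway other than MAPK14 (0.66). None of these other members passed alone, with or without the replicate block, and the permutation test takes no account of correlation between genes. Among the 25 lists, a permutation of gene labels also passed the 372 olfactory receptors, a control list (adjusted p = 0.017). With the block, HOXA13 (2.09 ± 0.08), ZBTB7A (1.67 ± 0.10), NFIL3 (1.66 ± 0.44), OTX1 (1.61 ± 0.21) and GSK3B (1.23 ± 0.65) were enriched as well. GSK3B encodes a kinase and the others encode transcription factors. Their guides were already abundant in vehicle replicate 1, with a mean log2(CPM + 1) of 8.9, 6.4, 7.6, 6.1 and 8.7 in this order. NLRP3, PYCARD, PIEZO1 and KCNN4 had 2.7, 4.4, 5.8 and 6.1 there. All HOXA13, NFIL3 and GSK3B guides lay above the non-targeting median of 826 reads in vehicle replicate 1, with at least 11439, 2450 and 6391. OTX1 and ZBTB7A each had a guide below it (564 and 697). The PIEZO1 and KCNN4 guides spanned 278 to 21994 and 713 to 11692 reads there. Guides against HOXA13, NFIL3 and GSK3B were thus more abundant than most control guides without R837 and Yoda1 too. Whether these knockouts outgrow other cells was not tested, as none of the 4 libraries came from before the culture.

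The treated libraries shared their abundant guides. Among 1480 guides with at least 5000 reads in treated replicate 1, the reads in treated replicate 2 were a median of 0.568 times as many (5th to 95th percentile 0.428 to 0.791). The same selection acting separately on 2 populations stays open: over 984 non-targeting guides, the SD of the log2 ratio between replicates was 0.733 in treated and 0.815 in vehicle libraries, a ratio of 0.90 (95% bootstrap interval 0.857 to 0.944), which does not decide because drift of the vehicle cultures was not measured. Material of the replicate 1 population in treated replicate 2 may contribute and stays open as well: for 25 guides at least 8 times higher in vehicle replicate 1, treated replicate 2 lay at 0.099 of the way from vehicle replicate 2 (quartiles 0.0571 and 0.160), but treated replicate 1 itself lay at 0.277. These positions cannot decide, because the guides were chosen on the same vehicle levels that set the scale. In the reverse direction only 1 guide was at least 8 times higher in vehicle replicate 2. Expansion of a common pool for different lengths of time was not tested and stays open, with the Gini index at 0.447 in vehicle replicate 2, 0.628 in treated replicate 2, 0.633 in vehicle replicate 1 and 0.753 in treated replicate 1.

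Few abundant guides rose far past one common factor, called the ceiling here, and some lay well below it. The GSK3B guides had 12176 to 63226 treated reads in replicate 1 and rose 1.84 to 2.33 times. The ceiling was the median raw read ratio of the 36 most abundant treated guides, 6.61 and 7.01 in replicates 1 and 2. Scaled on non-targeting guides it was 5.48 and 4.97. The 16 guides of PIEZO1, KCNN4, PYCARD and NLRP3 had raw medians of 6.80 and 7.42. The guides compared with this ceiling had at least 5000 reads in the treated library. In replicate 2 a guide against FKBP5 went from 647 to 11754 reads, 2.59 times past this ceiling, and a guide against PIEZO1 went from 1058 to 11176, the other of 2 such guides more than 1.5 times past it, which argues against treated material in the vehicle library as the whole cause there. In replicate 1 the highest ratio of such a guide was 8.48, for TBX2, or 1.28 times the ceiling, so treated material in vehicle replicate 1 and an equal gain of all cells that survived in full (ceiling over the median of the 4 genes, 0.972) cannot be told apart, because both predict the same ratio. Either could set the upper bound of the changes of PIEZO1, KCNN4 and PYCARD in replicate 1.

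Guides of unrelated genes had nearly equal counts. The top guides of PDE1C and NTN5 had 69008 and 68146 reads in vehicle replicate 1, 33504 and 32300 in vehicle replicate 2, 464017 and 461997 in treated replicate 1, and 252837 and 239415 in treated replicate 2. Several guides carried by 1 expanded clone may give such pairs, but 77 pairs of 231 guides matched within 10% in all 4 libraries, where 1000 permutations gave a mean of 82.5 and a highest of 115. No excess over the permutations was seen. A few clones would add few pairs to that background, so the test cannot exclude them. Matching pairs were no more frequent than in permutations of the library profiles among these guides, so their number needs no shared origin. No further explanation was tested.

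The 4 libraries can be split into 2 and 2 in 3 ways, too few for a share under 0.05. The real split called 18 genes and the highest other split called 7, so 1 of 3 splits reached the real count. The split by replicate number called 0 genes by rank aggregation (edgeR) but 7312 guides, where the real split called 0 guides, which points to a structure of the samples by replicate number. With the replicate block 3149 guides passed.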
